A study of Homo sapiens with 4 samples.

How the data were processed

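Total RNA of parental and cisplatin-resistant CAL-27 cells was measured on 4 NimbleGen 1-colour arrays, 2 per group. Per the labels' protocols, double-stranded cDNA was made with oligo-dT primers and labelled with Cy3 random primers and the Klenow enzyme. Both strands therefore carry dye, so that a gene and a transcript antisense to it, or an overlapping gene, cannot be told apart, and transcripts without a poly(A) tail are expected to be poorly covered. The deposited values are normalized intensity values per row and array on a linear scale, as read from the values themselves: the lowest was 8.79 and the highest lay near the limit of the scanner. Per the submitters' processing notes they were made with RMA, which corrects background, equalises the distributions of the arrays and summarises probes; its version, the filter on rows and the genome build were not given in the sources used here. No detection calls or background probes were used here, so a dim value has no stated bound, and folds of dim genes are nominal.

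Intensities were taken to log2 with no further normalization. A row was called coding where its identifier was a RefSeq mRNA accession (18473 rows) and non-coding otherwise (23679 rows). Gene symbols came from the platform annotation (17899 rows) and, through RefSeq accessions, from a RefSeq gene table of assembly GRCh38 (674 further rows), each of these 18573 rows having 1 symbol and 0 rows having several. This left 726 coding and 22853 non-coding rows without a name. The named non-coding rows held 444 long non-coding or antisense RNAs and 335 transcribed pseudogenes by that table, and 25 rows named after protein-coding genes. For tests by gene, the row with the highest mean over the 4 arrays stood for the gene, giving 15073 genes, of which 2816 had more than 1 row; where rows of a named gene differed by over 0.5 on the log2 scale, their range or the other row's value is given. Symbols are current ones, and near-identical gene copies such as keratins of 1 subfamily may share probe signal.

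Resistant and parental arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior variance, no covariates), with Benjamini-Hochberg adjustment over all rows or over all genes and a threshold of 0.05. Differences are resistant minus parental on the log2 scale with limma's moderated standard error. A gene is said to have risen or fallen where it passed the test over all genes; the test over all rows was the main comparison of the study's transcripts, and the test over genes was set out with the gene lists, although its total count was added after the data had been seen. The 29 gene lists, the test and its threshold, the rule for named genes and the main alternatives were fixed before the data were examined. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 (661 of 874 listed genes were measured), and again with an estimated correlation and with fry, whose test asks whether the genes of a list move one way on balance without comparing them with other genes. Of the 6 lists called with the preset correlation, 0 held with an estimated correlation. The latter setting rests on the few residual degrees of freedom of the 4 arrays and so has little power here. The lists covered platinum and drug transport, glutathione and metallothionein, NRF2 targets, nucleotide excision and crosslink repair, mismatch repair and translesion synthesis, p53 targets, apoptosis, mesenchymal genes, epithelial junctions and keratins, squamous differentiation, stemness, Wnt targets, interferon-stimulated genes, NF-kB and cytokines, cell cycle, unfolded protein and amino acid stress, cholesterol and fatty acid synthesis, hypoxia and glycolysis, receptor tyrosine kinases, cancer testis antigens, HOX genes, ribosomal proteins, reference genes, histones, cancer-related long non-coding RNAs, and markers of fibroblasts, leukocytes, endothelium and simple epithelium.

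Named genes followed a rule. It took the 10 rows with the largest rise and the 10 with the largest fall in each class among rows past the threshold and separated between the groups. Since 0 rows passed, these places were filled by the smallest p. The rule gives such genes as values only, so where they are said to have risen or fallen this rests on the test over genes alone. It also took up to 4 members of each list with the smallest p, the long non-coding RNAs UCA1, KCNQ1OT1, MALAT1, NEAT1, HOTAIR and H19 where measured, and at most 2 unnamed rows that rose and 2 that fell by the largest change. KRT5 and KRT17, and KRT18, EPCAM and CDH1, which the plot of single genes shows, lie outside this rule and were chosen after their values were seen. Some genes that the rule takes are not reported here.

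The scripts were tested on simulated data in which 200 rows were changed. Noise was drawn with a shared SD per bin of mean intensity, averaged from the real arrays, so single rows had no spread of their own. On 42152 such rows, the constant prior variance called 0 of 100 rows changed by 1 on the log2 scale and 0 of 100 changed by 3. The prior variance following intensity called 8 and 62 of them and 3 unchanged rows. The noise has the form that the latter prior assumes, so the simulation favours it and does not rank the priors for the real arrays. With so few rows changed, the adjustment is also harsher than where many rows differ. On 15073 genes the constant prior called 0 of 100 and 0 of 100, and the prior following intensity 31 and 91, with 10 unchanged genes called. A list shifted by -1 was found by camera with the preset correlation (adjusted p = 1.2e-18) and by fry (adjusted p = 0.0016) but not with an estimated correlation (adjusted p = 0.253). The simulated genes were independent, so the 0 other lists called say nothing about lists of correlated genes. With blocks of 30 neighbouring genes shifted together, the test of neighbouring genes gave r = 0.120, above 1000 shuffled orders, and r = 0.0077 without such blocks.

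The series describes the arrays as biological replicates of the cells, and the labels name 1 resistant line, so p-values measure the spread between these cultures and not between separate selections. No batch, slide or scan date was used here. Other settings tried were a replicate block, centring on the median, quantile normalization, leaving out the dimmest 25% or 50% of rows, a prior variance following intensity (trend and robust in eBayes), an unmoderated test with unequal variances, the mean of a gene's rows, leaving out dim members of the lists, and leaving out each array in turn. Cyclic loess, the alternatives by gene, and the joint use of the intensity prior with a left-out array or the block were added after the data had been seen.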

Results

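RNA of CAL-27 cells, an established line of human tongue squamous cell carcinoma, was hybridised to 1-colour arrays with probes for long non-coding and protein-coding transcripts. Parental cells were compared with a cisplatin-resistant derivative. Cisplatin is a platinum compound that crosslinks DNA, and per the labels the cells had met concentrations rising from 1e-07 M to 1e-05 M. Each group held 2 arrays, which the series describes as biological replicates. Each of the 4 arrays gave 42152 normalized intensities, of which 18473 had RefSeq mRNA identifiers and are called coding here. The other 23679 are called non-coding, although 25 of them carried the name of a protein-coding gene. The median intensity of an array lay between 141 and 149.9, and the highest value between 62616 and 65071. Across all rows, which are not independent of each other, log2 intensity correlated at r = 0.921 between the parental replicates and 0.946 between the resistant replicates. Between arrays of different groups r lay between 0.890 and 0.906. The difference between the parental replicates had an SD of 1.30 on the log2 scale for rows with a mean under 6 and of 0.37 for rows with a mean above 12. The corresponding SDs for the resistant replicates were 1.09 and 0.31. The number of arrays limits the precision of every value.

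The comparison asked which long non-coding RNAs and mRNAs differ between the resistant and the parental cells. In the resistant cells, 27 of 35 listed genes of squamous differentiation fell, while 19 of 27 listed NF-kB and cytokine genes rose; as whole lists they passed with a preset correlation but not with an estimated one (adjusted p = 0.231 and adjusted p = 0.350 with an estimated correlation). KRT14, a keratin of basal squamous cells, was 77.5-fold lower in the resistant arrays, a log2 difference of -6.28 ± 0.19 (difference ± SE, n = 2 arrays per group, adjusted p = 0.0165). IL6, an inflammatory cytokine, rose by 3.64 ± 0.18, which is 12.5-fold. H19, an imprinted long non-coding RNA, was 77.1-fold lower, with a difference of -6.27 ± 0.39. This fold is nominal, since the mean of H19 in the resistant arrays was dim (5.03). CCND2, which encodes cyclin D2, rose by 5.17 ± 0.19, which is 36.1-fold. These calls rest on limma's test over genes, whereas 0 rows passed when all rows were tested together (smallest adjusted p = 0.0606).

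With 1 row per gene, 919 of 15073 named genes passed limma's moderated test, 492 higher and 427 lower in the resistant arrays, each by at least 2-fold. The unmoderated test with unequal variances called 0 genes, but it also called 0 of 100 simulated rows changed by 3 on the log2 scale. With a replicate block, which leaves 1 residual degree of freedom, the count was 0, and jointly with a prior variance following intensity it was 3698. After median centring 458 genes were higher and 507 lower, so the balance of directions depended on the scaling. When all 42152 rows were tested together, limma called 0 rows (smallest adjusted p = 0.0606), and the unmoderated test also called 0. At an unadjusted p under 0.05, limma had 4350 rows higher and 3546 lower, of which 3396 and 2481 differed by at least 2-fold (2994 and 2878 after median centring). With limma's prior variance following intensity, called the intensity prior below, 2256 rows were higher and 2072 lower, and by gene 1571 were higher and 1846 lower. Both resistant arrays lay above or below both parental arrays in 51.6% of rows, where chance gives 33.3%. The count over genes was 0 when parental replicate 1, parental replicate 2, resistant replicate 1 or resistant replicate 2 was left out, which leaves 1 residual degree of freedom. With the prior variance following intensity, 836, 822, 746 and 736 of the 919 genes were still called without these arrays, in the same order.

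**Figure D1:**
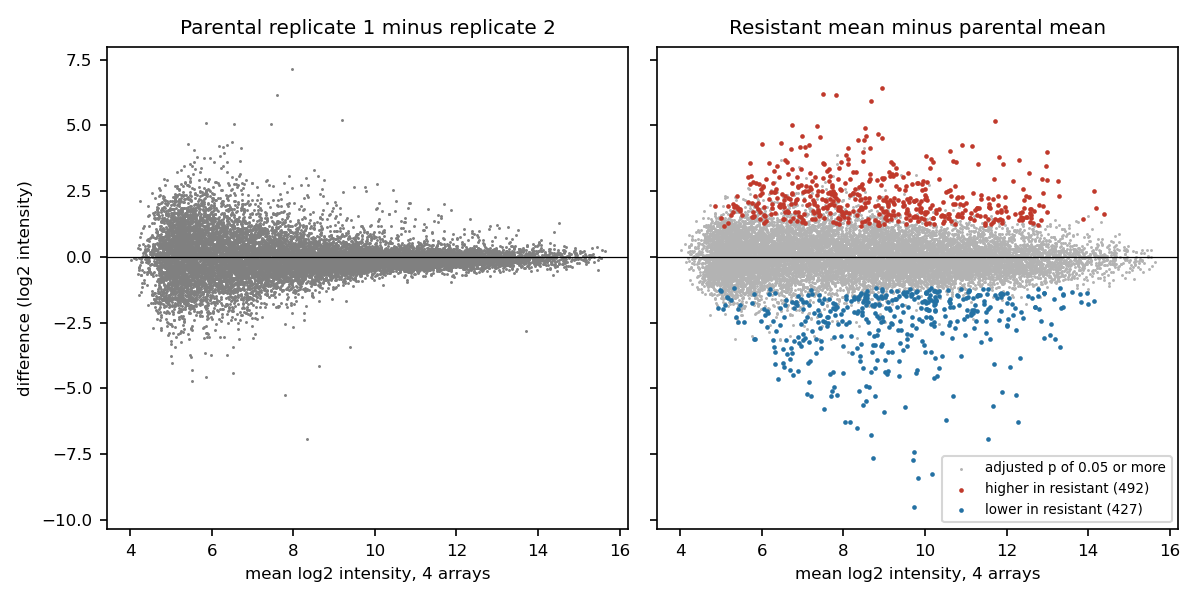
Left, the difference between the 2 parental replicates, and right, the resistant mean minus the parental mean, for 15073 genes (1 point per gene, log2 intensity) against the gene's mean log2 intensity over the 4 arrays. The spread between replicates narrows with intensity, and the 492 genes called higher and 427 called lower at an adjusted p under 0.05 are coloured.

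Most listed genes of squamous differentiation, which encode suprabasal keratins, cornified envelope proteins, kallikreins and serpins, fell. Of 35 measured members, 27 fell, 0 rose and 8 did not pass; adjusted over the list alone, 31 were lower and 1 was higher. The median difference was -2.99, with quartiles of -4.67 and -2.10. The list moved against all other genes in camera with a preset correlation (adjusted p = 2.3e-20). It did not pass with one estimated from the arrays (adjusted p = 0.231), although the estimate, -0.013, lay under the preset 0.01. The setting with an estimated correlation also missed a simulated shift of -1 on the log2 scale. KRT4 and KRT13, keratins of mucosal squamous epithelium, fell by 7.64 ± 0.31 and 5.30 ± 0.22. PI3, the protease inhibitor elafin (-6.19 ± 0.21), and SERPINB13, a serpin of squamous cells (-4.20 ± 0.18), fell too. Among the 29 measured genes of cell junctions and keratins, 8 fell, 2 rose and 19 did not pass, and adjusted over the list alone 11 were lower and 8 higher; the list as a whole did not pass (adjusted p = 0.197). KRT6A (-6.91 ± 0.26), the desmosomal plaque gene PKP1 (-6.52 ± 0.22) and DSP, which encodes desmoplakin (-3.11 ± 0.18), were among those that fell. KRT6A has close relatives whose probes it may share, so its value is less certain. The squamous keratin genes KRT5 (-0.44 ± 0.19, adjusted p = 0.236) and KRT17 (-0.79 ± 0.24, adjusted p = 0.140), chosen after their values were seen, did not pass over all genes. Both were lower with the intensity prior (adjusted p = 0.0236 and 0.0041), and KRT17 also when adjusted over the list alone. Their parental and resistant means (15.71 and 15.27 for KRT5, 15.31 and 14.52 for KRT17) lay near the top of the scale, where differences may be compressed. Of 13 measured markers of simple epithelium, AGR2 fell by 3.24 ± 0.45 and the other 12 did not pass (adjusted p = 0.758 for the list). KRT8, a keratin of simple epithelium, differed by 1.06 ± 0.30 (adjusted p = 0.123, and 0.0049 with the intensity prior). GATA3 differed by 2.39 ± 0.37 (adjusted p = 0.0501, and 0.0118 with the intensity prior). KRT19 differed the other way, by -0.85 ± 0.19 (adjusted p = 0.0856, and 0.0744 with the intensity prior).

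**Figure D2:**
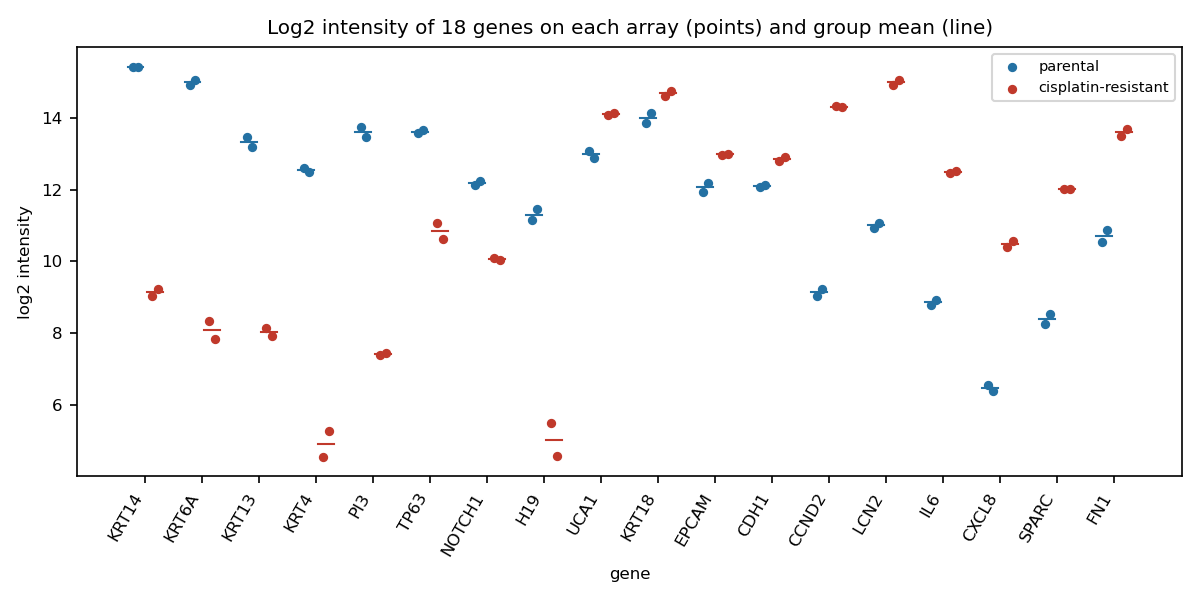
Log2 intensity of 18 genes on each of the 4 arrays (points) with the group mean (line), parental in blue and cisplatin-resistant in red. Both resistant arrays lie below both parental arrays for the squamous keratins KRT14, KRT6A, KRT13 and KRT4 and above them for LCN2, IL6, CXCL8, SPARC and FN1; UCA1, KRT18, EPCAM and CDH1 did not pass over all genes with a constant prior variance, but did with the intensity prior.

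Of the 27 measured members of the NF-kB and cytokine list, 19 rose, 1 fell and 7 did not pass; adjusted over the list alone, 22 were higher and 1 was lower. The median difference was 1.57 (adjusted p = 1.3e-12; adjusted p = 0.350 with an estimated correlation). CXCL8, a neutrophil chemokine, rose by 4.01 ± 0.19, LCN2, an iron-binding protein of innate defence, by 3.99 ± 0.19, and the cytokine gene TNF by 3.64 ± 0.18. Interferon-stimulated genes were higher as a list (median difference 0.41, adjusted p = 3.2e-05; adjusted p = 0.350 with an estimated correlation). In this list 2 of 46 measured members rose and 44 did not pass, and adjusted over the list alone 2 were higher; with the prior variance following intensity, 21 were higher and 1 lower. MX2 and GBP1, which encode antiviral GTPases, rose by 1.96 ± 0.24 and 1.30 ± 0.18. MX1 differed by 1.33 ± 0.22 (adjusted p = 0.0538; 9.3e-05 with the intensity prior). Of 14 leukocyte markers, 0 passed (adjusted p = 0.794 for the list), and LCP1, an actin-bundling protein, had the smallest p, with a difference of 1.27 ± 0.22 (adjusted p = 0.058; 0.0013 with the intensity prior).

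Mesenchymal genes were higher as a list (median difference 0.57, adjusted p = 1.1e-03; adjusted p = 0.704 with an estimated correlation). Of 25 measured members 4 rose and 21 did not pass, and adjusted over the list alone 10 were higher. VIM, also a listed gene, had no named row and was not tested. SPARC, a matrix glycoprotein, rose by 3.62 ± 0.20, and the collagen genes COL1A1 and COL5A1 by 3.23 ± 0.26 and 1.70 ± 0.25, although COL5A1 did not pass with the intensity prior (adjusted p = 0.0564). FN1, which encodes fibronectin, rose by 2.89 ± 0.22 in its brightest row, whereas its 3 rows ranged from -0.03 to 2.89. Of 10 measured fibroblast markers, 6 of which other lists also held, COL1A1 was the single gene that rose and 9 did not pass (adjusted p = 0.957 for the list). FBLN1 differed by -1.53 ± 0.26 (adjusted p = 0.0583, and 1.8e-04 with the intensity prior), with its 3 rows ranging from -1.70 to -0.75. DCN, which encodes the matrix proteoglycan decorin, differed by -0.57 ± 0.19 (adjusted p = 0.154) and PDGFRB by 0.96 ± 0.38 (adjusted p = 0.206). Among 7 endothelial markers, CDH5, which encodes vascular cadherin, rose by 5.02 ± 0.34, and the other 6 did not pass (adjusted p = 0.468 for the list). VWF, which encodes a clotting factor of endothelial cells, differed by 0.76 ± 0.18 (adjusted p = 0.0979). ERG and KDR differed the other way, by -1.25 ± 0.23 (adjusted p = 0.0665) and -0.61 ± 0.25 (adjusted p = 0.215).

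Genes of cholesterol and fatty acid synthesis were lower as a list (median difference -0.57, adjusted p = 7.5e-04; adjusted p = 0.704 with an estimated correlation). Of 22 measured members 4 fell and 18 did not pass, against 1 higher and 12 lower with the intensity prior. Adjusted over the list alone, 8 were lower. Among these were SREBF1, a transcription factor of lipid synthesis (-2.55 ± 0.21), FASN, the fatty acid synthase (-1.52 ± 0.18), and CYP51A1, an enzyme of sterol synthesis (-1.47 ± 0.21). The stemness list was lower (median difference -0.62, adjusted p = 0.040; adjusted p = 0.704 with an estimated correlation). Of 18 measured members 3 fell and 15 did not pass, and adjusted over the list alone 6 were lower and 1 higher. The 3 that fell are also genes of basal squamous epithelium, namely the transcription factor TP63 (-2.77 ± 0.24), the receptor NOTCH1 (-2.14 ± 0.18) and the integrin ITGA6 (-1.89 ± 0.23). The list's adjusted p was 0.143 without parental replicate 1, 0.0565 without parental replicate 2, 0.0816 without resistant replicate 1 and 0.0915 without resistant replicate 2. Of 26 genes of the unfolded protein and amino acid stress responses, 3 fell and 23 did not pass, and adjusted over the list alone 9 were lower and 1 higher. The 3 were the amino acid transporter gene SLC7A5 (-1.79 ± 0.19), the serine synthesis gene PSAT1 (-1.78 ± 0.21) and TRIB3, a stress-induced pseudokinase (-1.41 ± 0.21). That list did not pass (adjusted p = 0.0663), although it did without resistant replicate 1 (adjusted p = 0.0408) and with the prior variance following intensity (adjusted p = 0.021).

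Lists chosen for the handling of platinum and of DNA damage did not pass with camera, whereas fry called the NRF2, apoptosis and glutathione lists (adjusted p = 0.016, 0.016 and 0.0296). Listed genes without a named row were not tested. Only 17 of 24 transport genes and 16 of 31 glutathione and metallothionein genes were measured, and the export pump genes ABCB1 and ABCG2 were not. Of 17 measured transport genes none rose or fell (adjusted p = 0.563 for the list); ABCC3, an export pump, differed by 1.01 ± 0.19 (adjusted p = 0.0693; 0.0024 with the intensity prior) and ATP7B, a copper pump, by 1.06 ± 0.26 (adjusted p = 0.101). None of 26 genes of nucleotide excision and crosslink repair passed (adjusted p = 0.462 for the list), with BRIP1, a helicase of crosslink repair, at 1.14 ± 0.21 (adjusted p = 0.0644; 0.0074 with the intensity prior). With that prior 1 transport gene was higher and 1 lower, and 2 excision and crosslink repair genes were higher and 4 lower. It also called 0 higher and 4 lower in the glutathione list, and 3 and 6 among NRF2 targets. Among p53 targets it called 5 higher and 3 lower, and among apoptosis regulators 7 and 3. Mismatch repair and translesion synthesis had 0 of 13 genes past the threshold (adjusted p = 0.855 for the list). In the glutathione and metallothionein list, GSR, the glutathione reductase, fell by 1.89 ± 0.18 and the other 15 did not pass (adjusted p = 0.197 for the list). Among 26 NRF2 targets, 4 fell, 1 rose and 21 did not pass (adjusted p = 0.211 for the list). ALDH3A1, an aldehyde dehydrogenase, fell by 3.24 ± 0.20 and PIR by 2.35 ± 0.20 (-1.54 in its other row), while AKR1B1, an aldose reductase, rose by 2.23 ± 0.23. Of 22 p53 targets, GDF15, a stress cytokine, rose by 3.84 ± 0.19, PHLDA3 fell by 2.43 ± 0.19 and 20 did not pass (adjusted p = 0.794 for the list). Among 26 apoptosis regulators 3 rose and 23 did not pass (adjusted p = 0.181 for the list). BMF and BCL2L11, which encode death-promoting proteins, rose by 2.13 ± 0.20 and 1.57 ± 0.19, and BIRC3, an inhibitor of apoptosis, by 2.47 ± 0.25. Adjusted over the list alone, 0 genes passed in the transport, excision repair and mismatch repair lists, 1 was lower in the glutathione list, 3 were higher and 4 lower among NRF2 targets, 2 higher and 3 lower among p53 targets, and 5 higher and 3 lower among apoptosis regulators.

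In the list of receptor tyrosine kinases and their ligands, 4 of 29 measured members fell, 2 rose and 23 did not pass (adjusted p = 0.794 for the list). The receptor gene FGFR3 (-4.52 ± 0.32) and the ligand gene AREG (-1.73 ± 0.21) fell, while the phosphatase genes DUSP4 and DUSP5 rose by 3.08 ± 0.41 (4.13 in the other row of DUSP4) and 2.30 ± 0.18. Of 21 Wnt targets, 3 rose, 1 fell and 17 did not pass (adjusted p = 0.238 for the list). MMP7, a matrix protease, rose by 4.01 ± 0.19, AXIN2, a Wnt feedback inhibitor, by 2.82 ± 0.21 and JUN by 2.41 ± 0.18, and DKK3 fell by 1.56 ± 0.21 (-2.10 in its other row). Among 35 HOX genes, 5 rose, 1 fell and 29 did not pass (adjusted p = 0.473 for the list). HOXB9, HOXB6 and HOXB4 rose by 2.16 ± 0.19, 2.01 ± 0.24 and 1.89 ± 0.23, and HOXA7 fell by 1.72 ± 0.18. Hypoxia and glycolysis genes went both ways, 3 rising, 4 falling and 15 of 22 not passing (adjusted p = 0.794 for the list). The glucose transporter gene SLC2A1 fell by 1.93 ± 0.19 and its relative SLC2A3 rose by 1.72 ± 0.19. Of 45 cell cycle genes, E2F2, an S-phase transcription factor, fell by 1.31 ± 0.19 and 44 did not pass (adjusted p = 0.211 for the list). With the intensity prior, 1 cell cycle gene was higher and 9 were lower. None of 21 cancer testis antigens, 25 replication-dependent histones, 27 ribosomal proteins or 11 reference genes passed (adjusted p = 0.794, 0.444, 0.529 and 0.794 for the lists). The oligo-dT priming limits what the histone result can show, and 10 of the 25 histones had a mean above 8 in parental and 12 in resistant arrays. The median difference of the reference genes was -0.00061, and over the 4 scalings it lay between -0.07 and 0.06. In some lists that did not pass, the median, the mean and the direction of the test differed in sign. HOX genes had a median of -0.04 and a mean of 0.29 and tested higher, fibroblast markers a median of -0.17 and a mean of 0.14 and tested higher, and reference genes a mean of 0.19 and tested higher. Receptor kinases had a median of 0.01 and a mean of -0.05 and tested higher, while cancer-related long non-coding RNAs, with a median of 0.00 and a mean of -0.16, tested lower. Ribosomal proteins (median -0.14, mean 0.00) and mismatch repair genes (median 0.01, mean -0.00) also tested lower. Adjusted over the list alone, 5 genes were higher and 4 lower among the receptor kinases, 3 higher and 1 lower among Wnt targets, 7 higher and 2 lower among HOX genes, and 4 higher and 5 lower for hypoxia and glycolysis. In the same way 1 gene was higher and 2 lower among simple epithelium markers, 2 higher and 1 lower among endothelial markers, and 1 higher and 1 lower among fibroblast markers, with 0 among leukocyte markers, cell cycle genes, cancer testis antigens, histones, ribosomal proteins and reference genes.

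**Figure D3:**
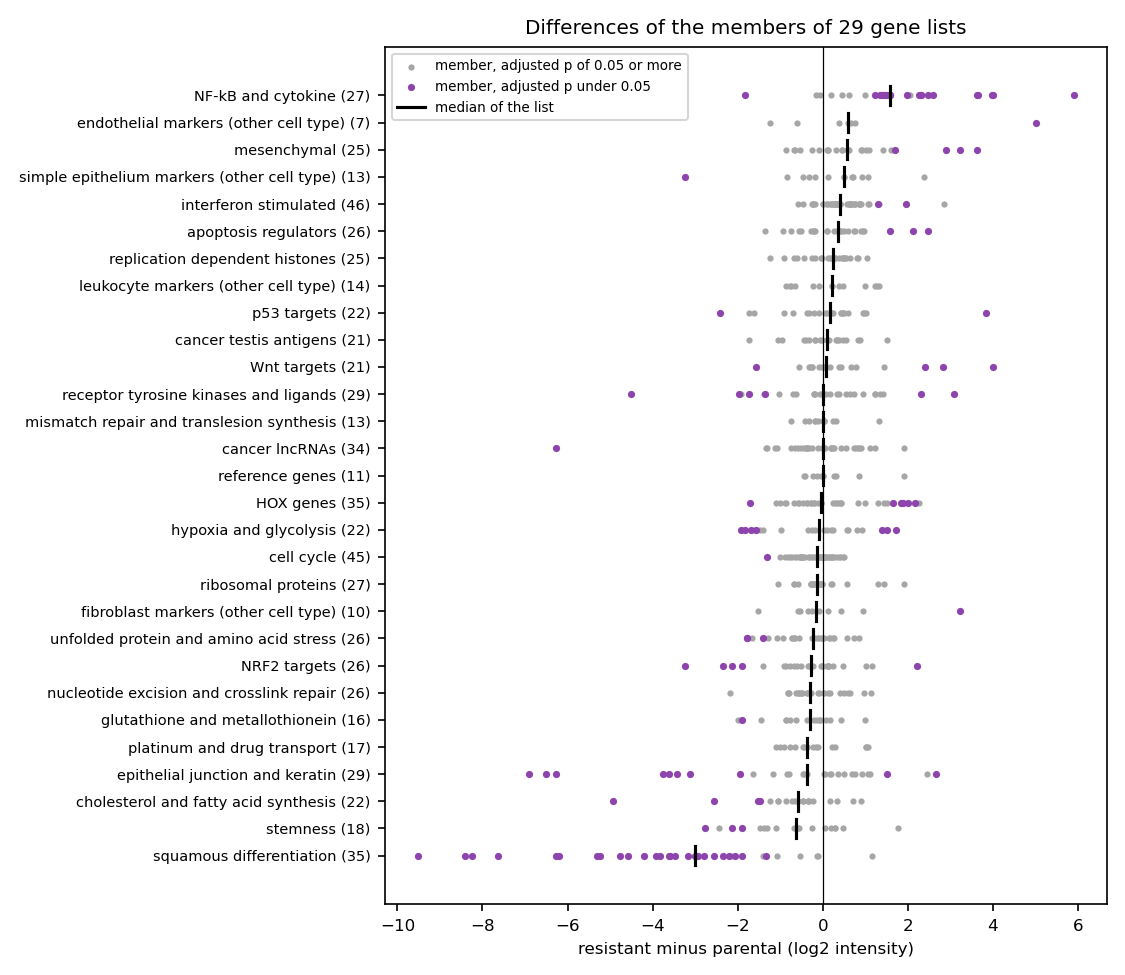
Resistant minus parental difference (log2 intensity) of each measured member of the 29 gene lists, with the median of each list as a black line and the number of measured members in brackets. The squamous differentiation list has the lowest median, -2.99, and the NF-kB and cytokine list the highest, 1.57.

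Large differences were also measured for other coding genes. DMBT1, which encodes a secreted mucosal scavenger receptor, rose by 6.14 ± 0.20 in its brightest row and by 3.09 in its other row. GIP, which encodes an incretin hormone, rose by 6.20 ± 0.22 and COXFA4L3 by 6.43 ± 0.25 (3.65 in its other row). SAA4, a serum amyloid gene, rose by 4.58 ± 0.20, and TMPRSS2, a membrane protease gene, by 4.66 ± 0.23. KRTAP5-1, ADAMTS9 and ADD2 also rose, by 4.23 ± 0.19, 4.30 ± 0.20 and 4.96 ± 0.43; the rows of ADD2 ranged from 2.07 to 4.96. Falls of similar size were seen for the collagenase gene MMP1 (-5.78 ± 0.19), the water and glycerol channel gene AQP3 (-5.66 ± 0.20), the connexin gene GJB6 (-5.29 ± 0.19), KCTD15 (-5.25 ± 0.57) and FGFBP1, which encodes a carrier of fibroblast growth factors (-5.14 ± 0.18). A mean near the bottom of the scale, such as 4.75 for DMBT1 in parental and 4.91 for KRT4 in resistant arrays, gives no reliable level, since no background measure was used here. RPLP0, a ribosomal protein gene of every cell, had a mean of 4.63 in the parental arrays, so a dim row is no proof of an absent transcript.

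Across rows, the replicates correlated at 0.874 (parental) and 0.919 (resistant) on non-coding and at 0.956 and 0.967 on coding rows; non-coding rows were dimmer, and these correlations were not compared at equal intensity. Of 780 genes whose brightest row was non-coding, 15 rose and 9 fell. When all rows were tested together, 0 of 23679 non-coding and 0 of 18473 coding rows passed limma's test; at an unadjusted p under 0.05, 2249 non-coding rows were higher and 1522 lower, and 2101 coding rows were higher and 2024 lower. With the prior variance following intensity, 912 non-coding rows were higher and 539 lower, against 1344 and 1533 coding rows. ANKRD30BP2, a transcribed pseudogene, rose by 4.12 ± 0.18, PRSS3P2 by 3.25 ± 0.27, PWARSN by 2.70 ± 0.18 and LINC00472 by 2.27 ± 0.18. The antisense transcripts GNAS-AS1, GNAO1-AS1 and RPL26L1-AS1 rose by 2.18 ± 0.19, 2.75 ± 0.34 and 2.18 ± 0.21 (0.55 in the other row of RPL26L1-AS1), but the labelling does not tell them from transcripts of the opposite strand. Besides H19, TPRXL (-4.02 ± 0.32), LOC93429 (-3.13 ± 0.36), ESPNP (-1.95 ± 0.18) and CEBPA-DT (-2.14 ± 0.31) fell. SNHG7 had a difference of -0.75 ± 0.18 (adjusted p = 0.0962; 0.0045 with the intensity prior) in its brightest row and of -1.69 in its other row, and SNHG29 one of -0.37 ± 0.18 (adjusted p = 0.272), with its 3 rows ranging from -1.71 to -0.37.

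In the list of cancer-related long non-coding RNAs, H19 fell and the other 33 of 34 measured members did not pass (adjusted p = 0.794 for the list). Adjusted over the list alone, 2 were higher and 3 lower, and with the intensity prior 5 were higher and 7 lower. UCA1, a long non-coding RNA abundant in squamous and urothelial tumours, had a mean log2 intensity of 12.98 ± 0.15 in parental and 14.10 ± 0.04 in resistant arrays (SD, n = 2 each). Its difference of 1.12 ± 0.19 did not pass (adjusted p = 0.0586), although it did with the prior variance following intensity (adjusted p = 1.7e-04). MALAT1, a nuclear RNA of most cells, differed by -1.07 ± 0.26 (adjusted p = 0.0959; adjusted p = 0.0076 with the prior variance following intensity). HOTAIR, transcribed from the HOXC cluster, differed by 0.20 ± 0.44 (adjusted p = 0.81). SNHG15 and DLEU1 differed by -1.31 ± 0.23 (adjusted p = 0.0619; 4.2e-04 with the intensity prior) and -1.12 ± 0.22 (adjusted p = 0.0696; 0.0041 with the intensity prior). KCNQ1OT1 and NEAT1 were not analysed here, as no row carried these names. Most non-coding rows, 22853 of 23679, could not be named. Of these, ASLNC08201 and ASLNC05042 had the largest rises among rows called with the prior variance following intensity, with differences of 5.34 ± 0.33 (adjusted p = 2.8e-04) and 5.17 ± 0.40 (adjusted p = 2.9e-04). ASLNC02979 and ASLNC11373 had the largest falls, -6.40 ± 0.30 (adjusted p = 6.9e-06) and -6.38 ± 0.43 (adjusted p = 2.8e-04). Each of these 4 rows had an adjusted p of 0.0606 with a constant prior variance, which is the fit that gave the SEs.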

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

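The settings by gene, cyclic loess and the joint settings were chosen after the results were seen. For rows, 1069 passed without the dimmest 25% (all at least 2-fold; 690 coding, 379 non-coding), 3452 without the dimmest 50% (2811 at least 2-fold; 2253 coding, 1199 non-coding) and 4328 with the prior variance following intensity (3035 at least 2-fold; 2877 coding, 1451 non-coding), against 0. The cause was not tested. The count of 5877 rows at least 2-fold apart at an unadjusted p was 3481 without the dimmest 50% and 2252 with the unmoderated test. By gene, 919 became 1796 and 2751 without the dimmest 25% and 50%, 3417 with the intensity prior, and 0 with the unmoderated test; median centring, quantile normalization, cyclic loess and the mean of a gene's rows gave 965, 958, 962 and 1087, and called 885, 902, 891 and 881 of the 919. The share of called genes that were higher was 53.5%, and 47.5% after median centring. With any 1 array left out the lone array is assumed to vary like the other group, and the counts were 0 for rows and 0 for genes; jointly with the intensity prior they were 3318, 2483, 1479 and 1472 rows and 2736, 2381, 1900 and 1970 genes without parental replicate 1, parental replicate 2, resistant replicate 1 and resistant replicate 2, and of these rows 2030 were higher and 1288 lower, 1590 and 893, 662 and 817, and 632 and 840, so the balance of directions turned with the array left out. The median difference of all rows lay between -0.07 and 0.00 over the scalings.

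The groups share replicate numbers, which the labels do not describe as pairs, and the numbers were not read as a pairing. The deviations of same-numbered arrays correlated at 0.163 over all rows, which with only 2 such pairs leaves open whether they belong together. With the replicate block the count by gene was 0, and jointly with the intensity prior it was 4930 rows and 3698 genes; the stemness list had an adjusted p of 0.0703 with the block, and no other list's call changed with it.

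For gene lists, 6 were called with the preset correlation, 0 with an estimated one and 16 with fry. With the estimated correlation the adjusted p was 0.231 for squamous differentiation, 0.350 for NF-kB and cytokines and for interferon-stimulated genes, and 0.704 for mesenchymal, cholesterol and stemness genes. The estimate lay under the preset 0.01 for squamous differentiation (-0.013), stemness (-0.0038) and interferon-stimulated genes (0.0044), so correlated genes do not account for their lost calls. It lay above 0.01 for NF-kB (0.053), mesenchymal (0.110) and cholesterol genes (0.154). With an estimated correlation, camera takes its p-values from the few residual degrees of freedom of the 4 arrays. With the preset correlation its degrees of freedom follow the number of genes. The setting also missed the shift simulated in independent genes, so a lost call alone points neither to correlated genes nor to a weak list. Where the estimate lay above 0.01, the part of the correlation in the lost call was not separated. Fry added the NRF2, apoptosis, endothelial and junction lists (adjusted p = 0.016 each), the HOX, Wnt, long non-coding RNA, glutathione and unfolded protein lists (adjusted p = 0.0296 each) and ribosomal proteins (adjusted p = 0.0473). The stemness list rose above the threshold with median centring (adjusted p = 0.0516), without the dimmest 25% (0.0883) or 50% of rows (0.148), with the mean of a gene's rows (0.0954), without its dim members (0.0699) and without single arrays (0.0565 to 0.143). The unfolded protein list passed with the intensity prior (adjusted p = 0.021) and the mean of a gene's rows (0.0462), and ranged from 0.0408 to 0.156 without single arrays. Directions that turned belonged to lists that did not pass: HOX genes without the dimmest 50% of rows (adjusted p = 0.9997) or without dim members (0.907), cancer testis antigens without the dimmest 25% (0.978), and fibroblast markers after quantile normalization (0.998). Without single arrays, turned directions occurred for the list of fibroblast markers (adjusted p 0.712 to 0.880), the list of mismatch repair and translesion synthesis (0.688 to 0.885), the list of receptor tyrosine kinases and ligands (0.546 to 0.980) and the list of replication dependent histones (0.0651 to 0.863); the values turned were 0.863 and 0.785 for fibroblast markers, 0.859 and 0.885 for mismatch repair, 0.911 for receptor kinases and 0.863 for histones. The cause was not tested for any of these lists.

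The 150 named genes gave 1914 values under other settings. Of these 1278 kept direction and side of the threshold, 531 kept direction but no longer passed, 104 newly passed and 1 turned: HOTAIR, 0.20, ranged from -0.35 without parental replicate 2 to 0.75 without parental replicate 1. Signal over background could not be assessed, and for rows with a mean log2 intensity under 6, where replicates differed with an SD of 1.30 and 1.09, small differences are not resolved.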

Other observations

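The genes in the opening paragraphs and the tests on the squamous genes and on antisense names were chosen after the results were seen; the tests on neighbouring genes and on the lean between transcript classes were set out before their results. These genes were picked singly, no list of such genes was tested, and they stand for no group. Of single acute-phase and complement genes that passed limma's test over all genes, SAA1 differed by 3.54 ± 0.21, SAA2 by 3.63 ± 0.23 (2.95 in its other row), complement C3 by 3.44 ± 0.21 and CFB by 2.90 ± 0.22 (log2 difference ± SE). In class II antigen presentation, HLA-DRA rose by 1.45 and HLA-DQB1 by 2.36, whereas HLA-DPB1 differed by 0.21. The matrix protease genes MMP10 and MMP13 fell by 5.65 and 4.95 beside MMP1, while MMP7 rose. The collagen genes COL6A2 and COL8A1 rose by 4.25 and 4.61 (2.47 in the other row of COL8A1) and COL17A1, a hemidesmosomal collagen, fell (-2.33). COL1A2 (-0.26), COL3A1 (-0.54), COL6A3 (0.43) and COL6A1 (1.01) did not pass, although COL6A1 did with the intensity prior (adjusted p = 0.0053).

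Some single genes of squamous cells outside the list also fell, without a count of those that did not. ZNF750 and FOXN1, transcription factors of epidermal differentiation, had differences of -3.51 and -4.89, TP73 of -3.60 and the surface gene LY6D of -7.40. The connexin genes GJB2 and GJB5 fell as well (-2.20 and -2.98).

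Squamous differentiation genes had a median difference of -2.99, and a technical origin was weighed. A remaining shift in scale between the deposited arrays is argued against by their medians, which lay between 141 and 149.9, and by the reference genes. The least negative median over 4 scalings was -2.99 and the most negative -3.06, while the reference genes stayed between -0.07 and 0.06. The scalings left the median difference of all rows between -0.07 and 0.00, so they could hardly have moved the squamous median, and its stability adds no support. All 4 start from values that were already normalized, so the normalization before deposit was not tested. Non-epithelial cells in place of the cancer cells were weighed with 15 epithelial genes that squamous and simple epithelia share. Their median difference was 0.69 (quartiles 0.18 and 1.08), far above the quartiles of the squamous list. These 15 genes were picked after the values were seen, so their median alone carries no verdict. They hold KRT7, KRT8, KRT18 and KRT19 of the simple epithelium list. They leave out desmosomal genes such as DSP (-3.11), PKP3 (-1.94) and JUP (0.03, with means of 15.46 and 15.49 near the top of the scale). All 29 measured junction and keratin genes, a list fixed before the data were examined, had a median of -0.38, which is lower but still above the squamous quartiles. Although 8 of them fell, 24 had a mean above 8 in resistant arrays, against 27 in parental arrays. For the 35 squamous genes these counts were 11 and 29. This argues against a full replacement of the cancer cells by non-epithelial cells. What stays open is whether the resistant culture is another line of epithelial cells or the same line in another state: 37 genes had a mean above 10 in parental and under 7 in resistant arrays and 15 a mean under 7 in parental and above 10 in resistant arrays, which either could give. A change of state during cisplatin selection may be the source, but the labels name 1 resistant line, so these explanations cannot be told apart here.

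Genes that lie next to each other on a chromosome, in the order of assembly GRCh38, differed alike. Over 8017 genes with a mean above 8, differences of genes 5 places apart correlated at r = 0.0700 across genes, which are not independent. This lay above the highest of 1000 shuffled orders (0.0444) and above the replicate differences (0.0018 and 0.0304). Adjacent genes, with shared name stems and overlaps left out, gave r = 0.149, so such pairs are not the whole cause. Related neighbours with different name stems stay in that set, so related genes side by side cannot be set aside. Among overlapping windows of 15 genes, 42 of 7695 had a median beyond the highest of 100 shuffles (1.04), such as SH3BGRL2 to SNHG5 (1.22, 14 of 15 genes the same way) and EPPK1 to SLC52A2 (-1.18, 14 of 15), while LCE1A to S100A4 (-2.98) and ATF5 to KLK11 (-1.90) hold squamous genes and kallikreins and CXCL1 to SEPTIN11 (1.12) holds chemokine genes of the cytokine list. Regional copy number or chromatin is a candidate explanation, and the array holds no DNA measurement that could separate these.

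Among rows called with the intensity prior, the odds of a higher rather than a lower call were greater for non-coding than for coding rows, with an odds ratio of 1.93 (95% interval 1.69 to 2.20; rows are not independent, so the interval is too narrow). An intensity-dependent shift between the groups may contribute, but within 9 usable of 10 bins of equal mean intensity the common odds ratio was 1.77 (1.55 to 2.02), which argues against it as the whole cause. No biological explanation was tested, and the ratio was not computed with single arrays left out.

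For 28 pairs of a gene and its antisense or divergent transcript by name, both with a mean above 8, the differences correlated across pairs at Pearson's r = 0.502 (permutation p = 0.00635, two-sided) and Spearman's rho = 0.486 (permutation p = 0.00948), with 22 pairs of the same sign. The labelling does not keep the strand, so this cannot be read as joint regulation.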
